A study of Homo sapiens with 96 samples.

How the data were processed

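RNA was measured in 16 human breast cell lines, each left unirradiated or given a single dose of 5 Gy and harvested 24 h later, per the labels' protocols. The series held 96 arrays in 32 groups of line and dose, with 3 arrays per group lettered A, B and C. The labels called the arrays triplicates and did not say that they came from separate cultures, so p-values within a line measure the spread between these arrays, which may be technical. The number of arrays limits the precision of every value.

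The values were deposited log2 expression values of 22277 probe sets of an Affymetrix human expression array, made with RMA per the submitters' processing notes. The RMA version was not given in the sources used here. RMA corrects background, normalizes between arrays and summarises the probes of each probe set. Array medians lay between 6.46 and 6.61, no 2 columns were identical (0 pairs), and no column was left unused.

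The array numbers in the labels fell into a series of 36 arrays (6 lines, called series 1 here) and a series of 60 arrays (10 lines, series 2). Series 1 held T47D, ZR751, MCF7, MDA-MB-231, SUM159 and SUM149, and series 2 held the other 10 lines. In all 22277 probe sets the mean and the SD over arrays were equal in both series within a tolerance of 1e-06. The mean differences between the series had an SD of 2.21e-10, against 0.236 to 0.466 in 20 random splits of the lines. The labels and file header do not state this matching step. Series 1 values ranged from 2.43 to 14.57 and series 2 values from -1.88 to 18.84. Levels are therefore not comparable between the series. If the step was a rescaling of each probe set by a positive factor, changes in series 2 keep their sign, but their size is on a scale particular to the probe set. A spread pooled over both series mixes these scales. No scanner files were used here.

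Gene symbols came from the platform annotation supplied with the data. It gave 1 symbol for 19070 probe sets, several for 1043 and none for 2164, and 62 control probe sets were left out. Of the probe sets with 1 symbol, 19058 were matched through their Entrez identifier and 0 symbols changed. Each gene was represented by the probe set with the highest mean over all arrays, which gave 11963 genes, 4310 of them with several probe sets. Probe sets whose identifier ends in _x_at contain probes shared with other sequences, which applied among others to THEMIS2, FBXO2, SKP2, HLA-F, HLA-B, HSD17B7, GDF15 and PTGDS. No genome build was given with the data, so no coordinates are reported.

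The design text names a mixed model with dose and subtype and their interaction. In this balanced design its line-level part was computed by averaging the 3 arrays of each line and dose, taking 16 differences of 5 Gy minus 0 Gy, and testing them with limma 3.58.1 (lmFit, eBayes) in R 4.3.3. These differences gave the mean response of all lines, of the 7 luminal lines and of the 9 basal lines, the luminal minus basal difference of the response, and the difference between luminal lines labelled Her2-positive and Her2-negative. HCC1954, labelled basal and Her2-positive, counted as basal. The 16 line means at 0 Gy gave the unirradiated luminal minus basal difference. Responses of single lines came from 1 limma fit over all 96 arrays with 32 group means, and an F test of the line-by-dose contrasts tested whether responses differed between lines. The p-values were adjusted by Benjamini-Hochberg over the 11963 genes, and a gene was called at an adjusted p under 0.05.

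The 18 gene lists were p53 targets, mitosis, DNA replication, replication-dependent histones, double-strand break repair, type I interferon response, inflammatory cytokines and NF-kB targets, antigen presentation class I, apoptosis and death receptors, lysosome, cholesterol and fatty acid synthesis, unfolded protein and heat shock response, ribosomal proteins, luminal markers, basal epithelial markers, mesenchymal markers, HER2 amplicon, and leukocyte and endothelial markers. They were tested with limma's camera at its preset correlation between genes of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. In 11 of the 108 list results at the level of lines the mean, median and test differed in sign, and 0 of those 11 were called.

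The comparisons, lists, tests and naming rule were fixed before the data were examined. The rule named, for the mean response, the 12 largest rises and 12 largest falls among called genes with the same direction in at least 14 of 16 lines. It named the 5 largest called changes each way for each subtype, and the 10 largest differences each way for subtype and Her2 differences, or the 5 smallest p-values each way where fewer than 5 genes passed. It named the 10 largest differences each way at 0 Gy, the largest called rise and fall of each line, the 10 called genes with the largest SD over lines, and up to 4 members of each list by size of change. CDKN1A, MDM2, FAS, ESR1, ERBB2 and KRT5 were always included.

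Whether the letters A, B and C pair the arrays of a line across doses was checked from the correlation of same-lettered arrays' deviations from their group means. A line counted as paired where all 3 correlations exceeded 0.1. This held in 7 lines, all 7 in series 2 (AU565, BT549, CAMA1, DKAT, HCC1954, MCF10A and SKBR3), with correlations from 0.148 to 0.860. It did not hold in the other 9 lines, where the lowest was -0.443. The pairing comes from the data and not from the labels.

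The steps were tested on simulated data of 11963 genes with 200 genes changed. For the mean response, 95.5% of genes changed by 0.25 log2, 98.5% by 0.5 and 100% by 1 were found, with 9 false calls. For the luminal minus basal response the shares were 32.8%, 82.1% and 95.5%, with 7 false calls. For the difference at 0 Gy they were 1.49%, 22.4% and 50%, with 2 false calls. For a single line they were 13.4%, 41.8% and 90.9%, with 2 false calls. The F test found 50 of the 200 changed genes with 1 false call. With the 30 DNA replication genes shifted, camera also called 1 of the other lists. The simulated genes varied independently of each other, and neither the matching of the series nor the replicate letters were modelled. The single-line run had no other variation of the response between lines. The shares found need not hold for the real data.

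Alternatives covered quantile normalization, centring of arrays, a filter on dim genes, other handling of probe sets, a trended and robust prior, leaving out replicates or lines, the array series, a replicate block, the line as a random block, the set tests, lists without shared genes, the Her2 difference within series 2 (3 lines against 1), and the TP53 comparison with lines exchanged within each series. Normalization alternatives moved the median change of all genes by less than 0.1 log2 in each line. The change of the 3' minus 5' probe set signal, a sign of RNA quality, averaged 0.02 for GAPDH (SD 0.03) and 0.02 for ACTB (SD 0.11) over the 16 lines. For ACTB it ran from -0.16 in T47D to 0.24 in SUM159 and was 0.15 in HBL100, and whether this moved the changes of single lines was not tested. Within groups the lowest correlation between arrays was 0.983 in series 1 and 0.970 in series 2. Figures were drawn with matplotlib 3.10.9, numpy 2.4.6 and Python 3.11.15, and tables were read with version 1.17.8 of data.table.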

Results

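Expression was measured 24 h after 0 or 5 Gy in 16 breast cell lines, 7 labelled luminal and 9 labelled basal, with 3 arrays per line and dose. The luminal lines were T47D, ZR751, MCF7 and CAMA1, labelled Her2-negative, and AU565, BT474 and SKBR3, labelled Her2-positive. The basal lines were MDA-MB-231, SUM159, SUM149, BT549, DKAT, HBL100, MCF10A, MCF12A and the Her2-positive HCC1954. MCF10A, MCF12A and HBL100 are known as lines that were not derived from tumours. Values are log2 units, and changes are 5 Gy minus 0 Gy. Because the array series were matched in mean and spread probe set by probe set, sizes of change in series 2 are on their own scale, and for many comparisons between groups values are also given within each series.

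The first question was which genes responded to 5 Gy across all lines. Genes of DNA replication led the falls. CCNE2, a cyclin that drives entry into S phase, fell by 0.67 (SE 0.13, n = 16 lines, limma adjusted p = 0.0198, lower in 14 lines). MCM6, a subunit of the replicative helicase, fell by 0.50 (SE 0.10, adjusted p = 0.0189, lower in 15 lines). UNG, which removes uracil from DNA, fell by 0.45 (SE 0.07, adjusted p = 0.0104, lower in 16 of 16 lines). SKP2, part of a ubiquitin ligase for cell-cycle inhibitors, fell by 0.41 (SE 0.09, adjusted p = 0.0358, lower in 15 lines). The transcription factor MYC fell by 0.33 (SE 0.07, adjusted p = 0.0261, lower in 15 lines). Among the rises, IRF1, an interferon-induced transcription factor, rose by 0.25 (SE 0.05, adjusted p = 0.0308, higher in 15 lines). TAP1, the peptide transporter of antigen presentation, rose by 0.22 (SE 0.04, adjusted p = 0.0239, higher in 15 lines). RELB, an NF-kB subunit, rose by 0.27 (SE 0.06, adjusted p = 0.0467, higher in 14 lines).

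In all, 150 of 11963 genes were called, 86 higher and 64 lower after irradiation, with a median size of 0.17. Among them, 24 genes had the same direction in all 16 lines, of which 15 rose and 9 fell. The other large falls were GABPB1 (-0.35), the mismatch repair genes PMS1 (-0.29) and MSH6 (-0.26), the cohesin subunit STAG1 (-0.29, SE 0.04, adjusted p = 0.00727), C2CD5 (-0.28), the haem synthesis enzyme CPOX (-0.27) and FJX1 (-0.27). The other large rises were THEMIS2 (0.27, SE 0.05, adjusted p = 0.0125, higher in 16 lines), the growth factor GDF11 (0.27), the collagen gene COL6A1 (0.26), the adenylate kinase AK1 (0.25) and the ubiquitin ligase subunit FBXO2 (0.25). They were followed by QPRT (0.24), the Wnt signalling gene DVL3 (0.23), JARID2 (0.20) and WDR45 (0.20). The other 7 probe sets of COL6A1 changed by -0.02 to 0.08 and the other 2 of GDF11 by -0.01 and 0.02, and the other probe set of DVL3 by 0.05, so the sizes of these 3 rises rest on a single probe set each. In series 1 and series 2 the means were -0.76 and -0.61 for CCNE2 and 0.30 and 0.22 for IRF1. CDKN1A (0.29, adjusted p = 0.167), MDM2 (0.15, adjusted p = 0.366), FAS (0.25, adjusted p = 0.408), ESR1 (0.09, adjusted p = 0.429), ERBB2 (0.05, adjusted p = 0.616) and KRT5 (0.01, adjusted p = 0.866) were not called.

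These counts depended on the fit. With limma's trended and robust prior 0 genes were called (smallest adjusted p = 0.124, 2029 genes at an unadjusted p under 0.05 against 2138). In series 1 alone 0 were called by limma (1555 at an unadjusted p under 0.05), in series 2 alone 2 (1649), and 9 without MCF10A, MCF12A and HBL100. Leaving out 1 line gave 56 (DKAT) to 198 (BT474) genes. It was under 100 also without T47D (72), ZR751 (99), MDA-MB-231 (90), SUM159 (77), BT549 (94), CAMA1 (89), MCF10A (75) or SKBR3 (93). Leaving out replicate A, B or C gave 67, 55 and 23.

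**Figure D1:**
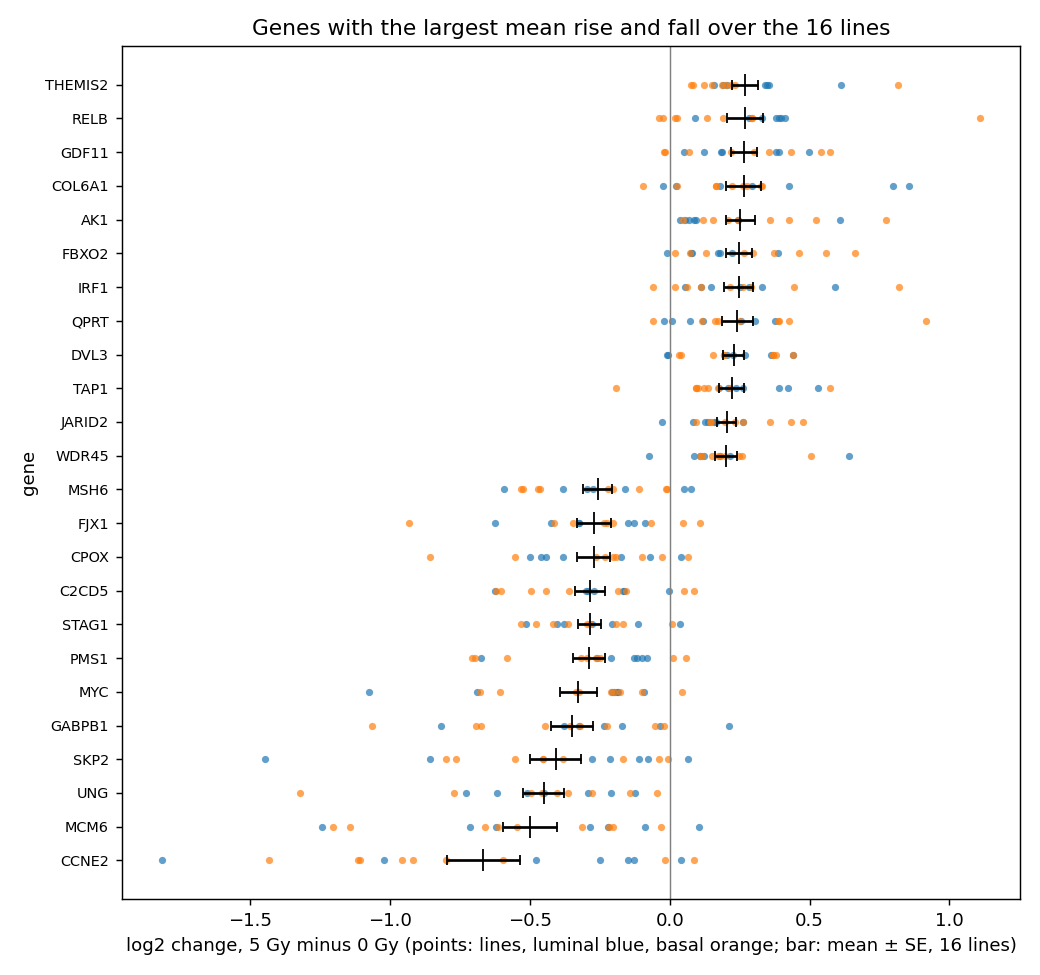
Log2 change (x axis, 5 Gy minus 0 Gy) of the 24 named genes (y axis), with a point per line (luminal blue, basal orange) and the mean ± SE over 16 lines as a black bar. The means run from -0.67 for CCNE2 to 0.27 for THEMIS2, and points of series 2 lines are on that series' own scale.

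Among the gene lists, DNA replication had the lowest mean. Its 30 measured members averaged -0.27 and 0 of them had a positive mean. Over all genes 3 fell (CCNE2, MCM6, UNG), and 12 fell adjusted over the list alone (list camera adjusted p = 1.35e-13, adjusted p = 0.387 with an estimated correlation). MCM5 had a value of -0.49 without passing (adjusted p = 0.0804). The 22 p53 targets averaged 0.16 and all 22 means were positive. None was called over all genes, and 2 were adjusted over the list alone (list camera adjusted p = 8.18e-07, adjusted p = 0.387 with an estimated correlation). The largest were CDKN1A, SESN1 (0.28) and TP53I3 (0.26). Double-strand break repair averaged -0.10 over 25 members, with 0 called over all genes and 2 lower adjusted over the list alone (camera adjusted p = 0.000770, adjusted p = 0.574 with an estimated correlation). Its mean was -0.27 in series 1 and -0.00 in series 2.

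The class I antigen presentation list averaged 0.14 and all 11 members were positive. Of these, 3 were called over all genes, among them TAP1 and HLA-F (0.17, SE 0.03, adjusted p = 0.0198, higher in 16 lines), and 8 adjusted over the list alone. The list had a camera adjusted p = 7.82e-09 (adjusted p = 0.1997 with an estimated correlation, fry adjusted p = 0.00343). Its mean was positive in all 16 lines, from 0.01 to 0.39. The type I interferon response averaged 0.13 with 32 of 33 members positive, 1 called over all genes (IRF1) and 8 adjusted over the list alone (camera adjusted p = 1.17e-08, adjusted p = 0.387 with an estimated correlation). RIGI (0.26) and IFIT1 (0.25) did not pass. NF-kB targets averaged 0.09 over 23 members, with RELB called, and 3 adjusted over the list alone (camera adjusted p = 0.00102, adjusted p = 0.410 with an estimated correlation). ICAM1 at 0.23 did not pass (adjusted p = 0.0633). The lysosome list averaged 0.06 over 22 members, 5 of them called adjusted over the list alone (camera adjusted p = 7.93e-05, adjusted p = 0.387 with an estimated correlation). Its 2 genes called over all genes were NEU1 (0.17, adjusted p = 0.0289) and MAN2B1 (0.16, adjusted p = 0.0309), which encode glycosidases. Apoptosis and death receptors averaged 0.06 with 0 of 25 called over all genes and 3 adjusted over the list alone (camera adjusted p = 0.0156, adjusted p = 0.387 with an estimated correlation). That list was not called in series 1 (adjusted p = 0.122) or without genes shared with other lists (adjusted p = 0.0652).

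The other 10 lists were not called. Mitosis averaged 0.02 over 32 members (camera adjusted p = 0.922), with opposite means of -0.26 in series 1 (adjusted p = 0.00181) and 0.19 in series 2 (adjusted p = 7.78e-06). These 2 p-values are at the preset correlation, whereas the correlation estimated over all lines was 0.94. In series 1 the mean of ZR751 was -2.24. Without ZR751 the list was called as higher over all lines (camera adjusted p = 3.09e-07). Histones averaged 0.02 (adjusted p = 0.935), cholesterol and fatty acid synthesis -0.02 (adjusted p = 0.935, with HSD17B7 called at 0.09), and the unfolded protein and heat shock response 0.02 (adjusted p = 0.935). Ribosomal proteins averaged 0.01 (adjusted p = 0.680), and luminal markers -0.04 (adjusted p = 0.170). The mean was 0.02 for basal epithelial markers (adjusted p = 0.551), 0.01 for mesenchymal markers (adjusted p = 0.560) and 0.02 for the HER2 amplicon (adjusted p = 0.435). Leukocyte and endothelial markers, which these cultures should lack, averaged 0.01 (adjusted p = 0.901).

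The next question was the response within each subtype. In the 7 luminal lines class I antigen presentation rose as a group. Its 11 members averaged 0.22 (camera adjusted p = 7.16e-17, adjusted p = 0.00612 with an estimated correlation). Of them 9 were called adjusted over the list alone, and the mean was 0.30 in series 1 and 0.16 in series 2. PSMB9, a subunit of the immunoproteasome, had a mean of 0.41, TAP1 0.32, PSMB8 0.27 and HLA-B 0.25 (SE 0.04, adjusted p = 0.107), and none of these passed over all genes. No gene was called in the luminal lines by limma (0 of 11963, 971 at an unadjusted p under 0.05, and 0 and 868 with the trended and robust prior). FAS (0.56, SE 0.22, adjusted p = 0.546) and CDKN1A (0.46, SE 0.16, adjusted p = 0.518) had large means with a large spread between lines.

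Other luminal lists were called only at the preset correlation. DNA replication averaged -0.35 (camera adjusted p = 7.16e-17, adjusted p = 0.263 with an estimated correlation) and double-strand break repair -0.14 (6.76e-05, adjusted p = 0.353 with an estimated correlation). The p53 targets averaged 0.21 (2.86e-07, adjusted p = 0.302 with an estimated correlation) and type I interferon response 0.15 (5.66e-08, adjusted p = 0.302 with an estimated correlation). NF-kB targets averaged 0.14 (3.23e-05, adjusted p = 0.270 with an estimated correlation) and apoptosis 0.09 (0.00150, adjusted p = 0.221 with an estimated correlation). The lysosome list averaged 0.08 (2.86e-07, adjusted p = 0.221 with an estimated correlation) and mesenchymal markers 0.09 (7.66e-05, adjusted p = 0.221 with an estimated correlation). The luminal p53 target mean was 0.49 in series 1 and 0.00 in series 2, the DNA replication mean -0.74 and -0.05, and the double-strand break repair mean -0.46 and 0.09. In the same order it was 0.26 and 0.07 for interferon response, 0.15 and 0.12 for NF-kB targets, and 0.13 and 0.06 for mesenchymal markers. Apoptosis (0.17 and 0.03, adjusted p = 0.0917 in series 2) and lysosome (0.17 and 0.02, adjusted p = 0.127 in series 2) were called in series 1 only, as were p53 targets (adjusted p = 0.860 in series 2) and DNA replication (adjusted p = 0.310 in series 2).

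In the 9 basal lines 26 genes were called, 15 higher and 11 lower. SEH1L, a nuclear pore component, fell by 0.27 (SE 0.04, adjusted p = 0.0155) and was lower in all 16 lines, and the cochaperone gene DNAJC22 rose by 0.29 (SE 0.04, adjusted p = 0.0155). The other named rises were CA11 (0.33), FBXO2 (0.32), BCAS4 (0.31) and the ATP-gated channel gene P2RX4 (0.27). The other named falls were STEAP1 (-0.36), STAG1 (-0.30), ARGLU1 (-0.28) and ZNF22 (-0.27, adjusted p = 0.0491), the rest at an adjusted p of 0.0429. Of the 4 lists called, none held with the estimate. The p53 targets averaged 0.12 (camera adjusted p = 0.00180) and DNA replication -0.20 (5.73e-06, 4 members lower adjusted over the list alone). Type I interferon response averaged 0.12 (5.24e-05) and class I antigen presentation 0.07 (0.00327), each with adjusted p = 0.881 with an estimated correlation. Basal means in series 1 and series 2 were -0.01 and 0.18 for p53 targets, -0.06 and -0.27 for DNA replication, 0.03 and 0.16 for interferon response and 0.11 and 0.05 for antigen presentation. In series 1 the p53 target (adjusted p = 0.935), DNA replication (adjusted p = 0.373) and interferon (adjusted p = 0.748) lists were not called. Without HBL100 the p53 target (adjusted p = 0.211) and interferon (adjusted p = 0.103) calls were lost, and without MCF10A, MCF12A and HBL100 the p53 target direction turned (adjusted p = 0.901). CCNE2 (-0.76, adjusted p = 0.0794), MCM6 (-0.55, adjusted p = 0.0842) and UNG (-0.48, adjusted p = 0.0603) did not pass in the basal lines.

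The basal calls were fragile. Limma called 0 with the trended and robust prior (1476 at an unadjusted p under 0.05, against 1613) and 0 in series 1 (917). It called 1 in series 2, 0 without MCF10A, MCF12A and HBL100, and 0 without BT549. Without another line the count was 1 (DKAT or MCF12A), 2 (HBL100), 4 (AU565), 5 (MCF7, MDA-MB-231, SUM159, CAMA1 or MCF10A), 6 (BT474), 8 (SKBR3), 14 (T47D), 15 (HCC1954), 52 (SUM149) or 90 (ZR751). Arrays centred on their median gave 17 higher and 7 lower.

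The response was then compared between subtypes. The class I antigen presentation list responded more in luminal than in basal lines by 0.14 (camera adjusted p = 6.88e-08, adjusted p = 0.0675 with an estimated correlation). The difference was 0.18 within series 1 and 0.11 within series 2. Mesenchymal markers, such as CAV2 (0.34), TGFBI (0.34) and the fibronectin gene FN1 (0.24), differed in the same direction by 0.13 (camera adjusted p = 6.24e-07, adjusted p = 0.0675 with an estimated correlation). All 18 members were positive, 3 were called adjusted over the list alone, and the difference was 0.15 and 0.11 within the series. Mitosis differed by -0.22 (camera adjusted p = 0.00523, adjusted p = 0.813 with an estimated correlation) and DNA replication by -0.14 (0.00722, adjusted p = 0.813 with an estimated correlation). These differences turned between the series, from -0.95 to 0.31 and from -0.67 to 0.22, and both turned without ZR751. The lysosome list differed by 0.04 (0.0129, adjusted p = 0.813 with an estimated correlation), 0.16 in series 1 and -0.04 in series 2.

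Limma called 0 single genes for this difference (454 at an unadjusted p under 0.05, 0 and 461 with the trended and robust prior, and 0 in either series). The smallest p-values belonged to SERPINA3, a protease inhibitor of the acute phase response (0.80, SE 0.15, adjusted p = 0.857, mean 0.66 in luminal and -0.13 in basal lines), PTGDS (0.54), HMGA2 (0.30), LFNG (0.27) and RUFY2 (0.36) on the higher side. On the lower side they were those of GTF2I (-0.40), METTL25B (-0.26), DNAJC22 (-0.25), C8B (-0.26) and TMEM187 (-0.36), and none of the 10 passed. The p53 target list was not called over both series (0.09, camera adjusted p = 0.163). Within the series it was called in opposite directions, at 0.49 in series 1 (camera adjusted p = 1.61e-10) and -0.18 in series 2 (camera adjusted p = 0.000169). The rises lay in ZR751 (0.76) and MCF7 (0.63), luminal lines of series 1, and in HBL100 (0.75) and MCF10A (0.32), basal lines of series 2. Every other line had a mean between -0.06 and 0.08. Both calls thus rest on these few lines, at the preset correlation, and do not show a difference between the subtypes as such.

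At 0 Gy the subtypes differed widely. Luminal lines had higher levels of the oestrogen receptor gene ESR1 (by 4.42, SE 1.07, adjusted p = 0.0147) and its known targets GREB1 (4.44) and TFF1 (4.43). Also higher were the luminal keratin gene KRT19 (4.42), AGR2 (4.40), the receptor gene ERBB3 (4.38), IGFBP5 (5.93, SE 0.75, adjusted p = 0.000195), SELENOP (5.17), ANXA9 (4.75) and EFHD1 (4.68). Basal lines had higher levels of the membrane-cytoskeleton linker MSN (-7.07, SE 0.33, adjusted p = 7.93e-09), vimentin (VIM, -5.85), caveolin 1 (CAV1, -6.01), NNMT (-6.38), GPX1 (-6.44), FSTL1 (-5.77), S100A2 (-5.69) and LOXL2 (-5.35). The inflammatory genes PTGS2 (-6.05) and CXCL2 (-5.50) were also higher in basal lines. In all, 1368 genes were called, 776 higher in luminal and 592 higher in basal lines. Within series 1 and series 2 the values were 6.05 and 3.46 for ESR1, -6.87 and -7.30 for MSN, and -5.94 and -5.89 for VIM. Within a series 108 and 504 genes were called, 33 of them in both, and 906 were called without MCF10A, MCF12A and HBL100.

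Luminal markers averaged 2.83 higher in luminal lines, all 21 positive and 15 called (adjusted p = 0.0338 with an estimated correlation). Mesenchymal markers averaged -3.10 with 12 of 18 called (adjusted p = 0.0132 with an estimated correlation). NF-kB targets averaged -2.38 (10 of 23 called, for instance CXCL3 at -5.00 and CXCL8 at -4.97, camera adjusted p = 9.59e-10, adjusted p = 0.0830 with an estimated correlation). Basal epithelial markers averaged -1.16, with 3 of 11 called, among them LAMB3 (-3.46) and ITGA6 (-3.16) (camera adjusted p = 6.85e-06, adjusted p = 0.0830 with an estimated correlation). KRT5 at -1.21 did not pass (adjusted p = 0.112). Class I antigen presentation averaged -1.01 (1 called, camera adjusted p = 5.67e-05, adjusted p = 0.230 with an estimated correlation). Type I interferon response averaged -0.79 (6 called, such as OASL at -2.40, 7.34e-06, adjusted p = 0.336 with an estimated correlation). Apoptosis genes averaged -0.40 (5 called, 0.00172, adjusted p = 0.0830 with an estimated correlation). The p53 targets averaged -0.38 (5 called, such as GADD45A at -1.35, 0.000353, adjusted p = 0.231 with an estimated correlation) and the lysosome list -0.32 (3 called, 0.00302, adjusted p = 0.230 with an estimated correlation). The p53 target difference was 0.21 in series 1 and -0.74 in series 2, and the interferon difference -0.09 and -1.24. In the same order the differences were 3.20 and 2.66 for luminal markers, -2.80 and -3.33 for mesenchymal markers, -2.80 and -2.15 for NF-kB targets and -1.01 and -1.27 for basal epithelial markers. They were -1.18 and -0.91 for antigen presentation, -0.37 and -0.43 for apoptosis, and -0.69 and -0.09 for lysosome, which was not called in series 2 (adjusted p = 0.179). The other 9 lists were not called over both series, among them mitosis (-0.08, adjusted p = 0.161), DNA replication (0.24, adjusted p = 0.225) and the HER2 amplicon (0.27, adjusted p = 0.160). Mitosis was called in opposite directions within the series (0.52, adjusted p = 0.00233, and -0.50, adjusted p = 5.79e-06). DNA replication was called in series 1 (0.56, adjusted p = 0.00325, and 0.03 in series 2), as was double-strand break repair (0.65, adjusted p = 0.00233, and -0.16). The HER2 amplicon was called in series 2 (0.51, adjusted p = 0.00546, and -0.09 in series 1).

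The HER2 receptor gene ERBB2 checked the Her2 labels within series 2. Its level at 0 Gy was 9.76 ± 0.02 (SD, n = 3 lines) in the luminal Her2-positive lines and 9.78 in HCC1954. It was 9.16 in CAMA1 and 8.97 ± 0.06 (SD, n = 5 lines) in the other basal lines. It was 0.45 higher in luminal than in basal lines (adjusted p = 0.0472), by 0.38 and 0.51 within the series. The spread of this probe set in series 2 equalled that in series 1, which held no line labelled Her2-positive. The sizes of these differences are on that matched scale, so only the order of the levels checks the labels.

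Among luminal lines, 8 lists were called as responding differently in those labelled Her2-positive, and none held with an estimated correlation. DNA replication was higher by 0.64 (camera adjusted p = 2.20e-18, adjusted p = 0.347 with an estimated correlation). Mitosis was higher by 0.62 (4.72e-07, adjusted p = 0.638 with an estimated correlation) and double-strand break repair by 0.43 (4.26e-10, adjusted p = 0.347 with an estimated correlation). Lower were p53 targets (-0.35, 1.67e-06, adjusted p = 0.448 with an estimated correlation) and type I interferon response (-0.21, 3.76e-05, adjusted p = 0.638 with an estimated correlation). So were class I antigen presentation (-0.15, 9.84e-06, adjusted p = 0.126 with an estimated correlation), apoptosis (-0.14, 0.0373, adjusted p = 0.448 with an estimated correlation) and lysosome (-0.13, 2.82e-05, adjusted p = 0.347 with an estimated correlation). Limma called 0 genes (717 at an unadjusted p under 0.05, and 0 and 687 with the trended and robust prior). The smallest p-values were those of GUCA1A (-0.58), KCNE4 (-2.11), TMEM45A (-0.48), KMT2D (-0.37) and HLA-F (-0.30), and of ZNF592 (0.28), SLC20A1 (0.34), PRRG4 (0.48), NOP14 (0.27) and CTPS1 (0.50), none passing. All 3 luminal Her2-positive lines were in series 2 and 3 of the 4 Her2-negative ones in series 1, so the Her2 label was nearly tied to the series. Within series 2 the 3 Her2-positive lines could be set against CAMA1 alone. There the mitosis difference was -0.49 (camera adjusted p = 3.13e-05, adjusted p = 0.899 with an estimated correlation), opposite to that over both series, and p53 targets differed by 0.02 (camera adjusted p = 0.995). DNA replication (0.28), type I interferon response (-0.16) and class I antigen presentation (-0.12) kept their direction and were called (camera adjusted p = 2.80e-05, 0.00652 and 0.00231, each with adjusted p = 0.899 with an estimated correlation). Double-strand break repair (0.04), apoptosis (-0.08) and lysosome (-0.04) were not called (camera adjusted p = 0.848, 0.174 and 0.323). Limma called 0 genes there (433 at an unadjusted p under 0.05). A single Her2-negative line cannot stand for its group. The mitosis difference over both series also turned without ZR751.

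Single lines differed in what responded. The p53 targets rose in ZR751 (mean 0.76, 14 of 22 members called, adjusted p = 2.75e-12 with an estimated correlation) and HBL100 (0.75, 16 called, adjusted p = 3.92e-14 with an estimated correlation). They also rose in MCF7 (0.63, 12 called, adjusted p = 1.13e-17 with an estimated correlation) and in MCF10A (0.32, adjusted p = 1.29e-10 with an estimated correlation). In MCF10A 2 members were called and 7 with the replicate letter as a block. MCF12A had a mean of 0.08 with 0 members called (adjusted p = 0.0486 with an estimated correlation), and the other 11 lines lay between -0.06 and 0.07. CDKN1A, the p53-induced inhibitor of cyclin-dependent kinases, rose by 1.81 in ZR751 (SE 0.10), 0.82 in MCF7, 0.47 in T47D, 0.45 in HBL100 and 0.37 in SUM159. MDM2, which targets p53 for degradation, rose by 1.05 in HBL100 (SE 0.13), 0.68 in MCF7 and 0.60 in ZR751. The death receptor gene FAS rose by 1.89 in MCF7 (SE 0.15), 1.87 in ZR751 and 0.51 in HBL100, and fell by 0.55 in SUM159. Each of these values compares 3 with 3 arrays in the limma fit of all lines. The MDM2 probe set used was dim, with a mean level of 5.46, against a median of 7.25 over all genes at 0 Gy. The other MDM2 probe sets lay lower, at 3.20 to 4.99. Over all lines they changed by 0.05 to 0.23 on average, against 0.15 for the one used.

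**Figure D2:**
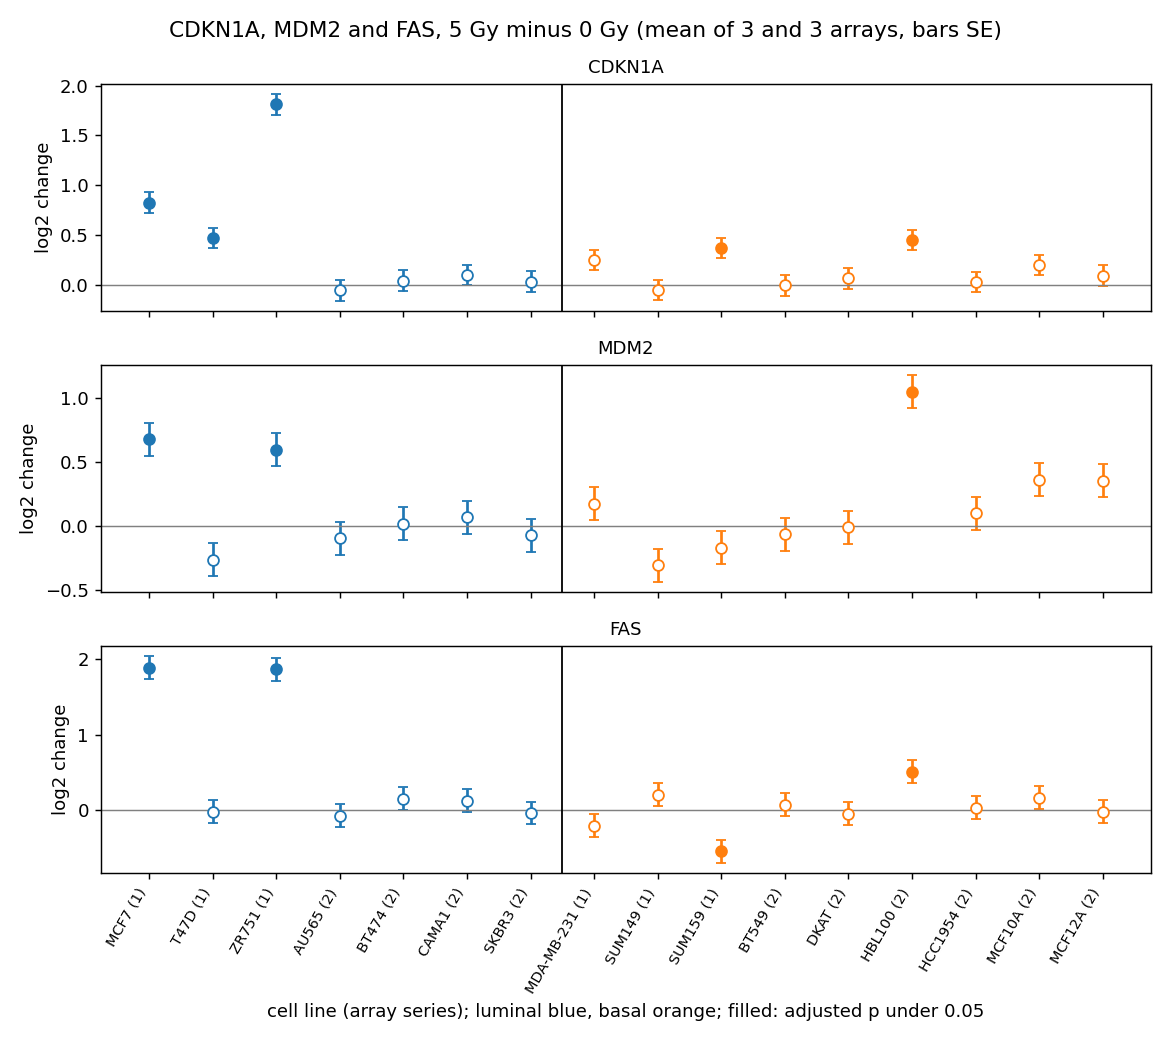
Log2 change (y axis, 5 Gy minus 0 Gy) of CDKN1A, MDM2 and FAS in each line (x axis, array series in brackets, luminal blue and basal orange), as means of 3 and 3 arrays with SE bars and filled points at an adjusted p under 0.05. ZR751, MCF7 and HBL100 are filled for all 3 genes, with CDKN1A highest in ZR751 at 1.81, MDM2 in HBL100 at 1.05 and FAS in MCF7 at 1.89. Values of series 2 lines are on that series' own scale.

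Proliferation genes moved in opposite directions between lines. In ZR751 all 32 mitosis genes fell (mean -2.24, adjusted p = 0.00281 with an estimated correlation), led by DLGAP5, a spindle protein gene that fell by 3.14. So did 29 of 30 DNA replication genes (mean -1.55, adjusted p = 0.000562 with an estimated correlation) and 17 of 25 double-strand break repair genes (-0.96, adjusted p = 0.00337 with an estimated correlation). In MCF10A 20 mitosis genes fell (mean -1.12, 31 with the block, adjusted p = 0.000764 with an estimated correlation), among them ASPM (-2.19). So did 4 replication genes (mean -0.65, 27 with the block, adjusted p = 0.000764 with an estimated correlation). In MCF7 21 replication genes fell (mean -0.79, adjusted p = 0.00187 with an estimated correlation) and 8 repair genes (-0.48, adjusted p = 0.00709 with an estimated correlation). In the same line 1 mitosis gene fell (mean -0.33, adjusted p = 0.370 with an estimated correlation). Mitosis means were positive in the other 13 lines. In CAMA1 the mean was 0.74 (adjusted p = 0.0413 with an estimated correlation) with 0 members called, 25 adjusted over the list alone and 24 with the block. In HBL100 6 mitosis genes rose (mean 0.63, adjusted p = 0.358 with an estimated correlation) and 13 replication genes fell (mean -0.47, adjusted p = 0.223 with an estimated correlation).

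**Figure D3:**
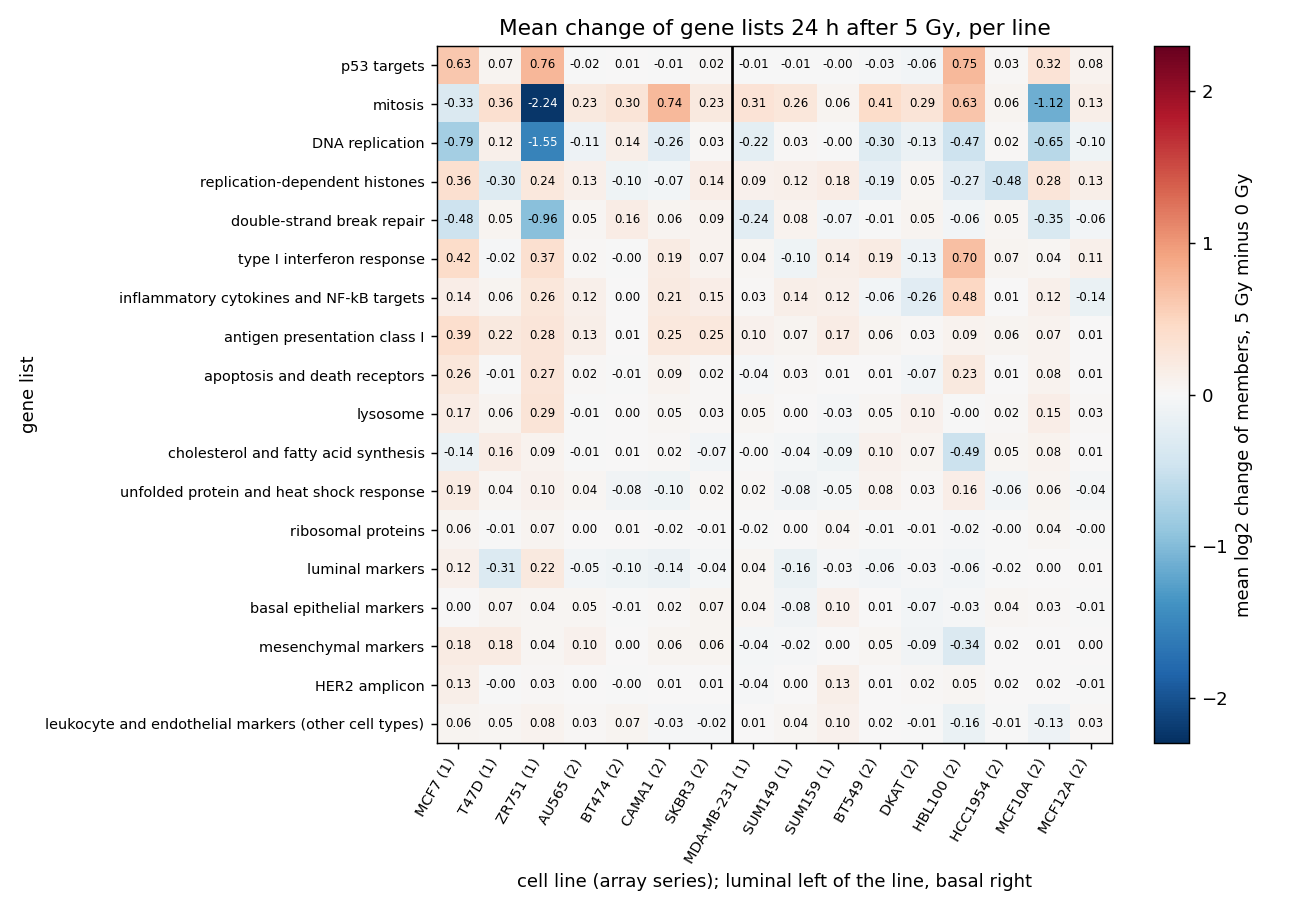
Mean log2 change (colour and number, 5 Gy minus 0 Gy) of the members of the 18 gene lists (rows) in each line (columns, array series in brackets, luminal left and basal right). Mitosis runs from -2.24 in ZR751 to 0.74 in CAMA1 and p53 targets from -0.06 in DKAT to 0.76 in ZR751, and series 2 values are on that series' own scale.

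Other lists were called in some of the lines. Replication-dependent histone genes averaged -0.48 in HCC1954 (1 called, 6 with the block, adjusted p = 1.86e-06 with an estimated correlation). They averaged 0.36 in MCF7 (4 called, adjusted p = 0.0463 with an estimated correlation) and 0.28 in MCF10A (1 called, adjusted p = 0.0477 with an estimated correlation). Luminal markers averaged -0.31 in T47D, where 3 fell (adjusted p = 0.0134 with an estimated correlation). In HBL100 12 interferon response genes rose (mean 0.70, camera adjusted p = 2.11e-11, adjusted p = 0.223 with an estimated correlation). There 7 cholesterol and fatty acid synthesis genes fell (mean -0.49, camera adjusted p = 2.52e-08, adjusted p = 0.221 with an estimated correlation) and mesenchymal markers averaged -0.34 (3 fell, adjusted p = 0.0273 with an estimated correlation). Interferon response genes were also called in MCF7 (mean 0.42, 2 rose, camera adjusted p = 8.54e-08, adjusted p = 0.252 with an estimated correlation) and ZR751 (mean 0.37, 5 rose, camera adjusted p = 0.00377, adjusted p = 0.713 with an estimated correlation). They were called, too, in CAMA1 (mean 0.19, camera adjusted p = 0.000965) and BT549 (mean 0.19, camera adjusted p = 0.00129), with 0 members called by limma in either line. In these 2 lines the list held with an estimated correlation only with the block (adjusted p = 0.00258 and 0.00604, against 0.681 and 0.695 without). Mesenchymal markers averaged 0.18 in MCF7 (3 rose, adjusted p = 0.0463 with an estimated correlation). In SUM159 no list was called although 729 genes were.

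The number of called genes ranged from 1809 in ZR751 (827 higher, 982 lower), 1194 in HBL100 (728 and 466), 729 in SUM159 (245 and 484), 368 in MCF7 (155 and 213), 348 in T47D (158 and 190), and 128 in MDA-MB-231 (49 and 79) down to 94 in MCF10A (6 and 88). It was 1 or 2 in 7 lines and 0 by limma in MCF12A (368 at an unadjusted p under 0.05) and SKBR3 (295). Arrays centred on their median gave 619 higher and 1131 lower genes in ZR751, 59 and 55 in MDA-MB-231 and 338 and 410 in SUM159. The counts also moved with the replicate left out. Without A, B or C they were 1626, 1115 and 958 in ZR751, 863, 414 and 446 in HBL100, 163, 126 and 104 in T47D and 163, 149 and 169 in MCF7. They were 1, 917 and 314 in SUM159, 695, 2 and 8 in MDA-MB-231 and 4, 0 and 116 in MCF10A. In the 7 lines whose letters paired the arrays, the block raised the counts to 422 in MCF10A, 320 in DKAT (from 1), 172 in CAMA1 (from 1), and 112 in BT549 (from 2). It gave 26 in SKBR3, 14 in HCC1954 (from 1) and 13 in AU565 (from 1). With it camera called 11 more of their 126 list results. Those 11 were NF-kB targets in AU565 (block adjusted p = 0.0201), DKAT (0.00216) and SKBR3 (0.00200) and interferon in DKAT (0.0293) and HCC1954 (0.0278). The others were antigen presentation (0.0286), lysosome (0.0286) and unfolded protein response (0.0155) in BT549, and apoptosis (0.0299), unfolded protein response (0.0177) and luminal markers (0.0240) in CAMA1, and none of these 11 held with an estimated correlation. Of the 126, 8 held with an estimated correlation without the block and 14 with it. The 6 gained were DNA replication (adjusted p = 0.00604) and interferon in BT549, DNA replication (0.0132), interferon and antigen presentation (0.00258) in CAMA1, and antigen presentation in SKBR3 (0.0119).

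The largest called changes were LAT2 (1.40) and CLDN8 (-1.23) in T47D, the stress cytokine GDF15 (2.19) in ZR751, and TRMT2B (-1.48) in MCF7. They were FOXD1 (0.86) and the oxytocin receptor gene OXTR (-0.92) in MDA-MB-231, and PLCG2 (0.83) and the lysosomal membrane gene SCARB2 (-1.19) in SUM159. In series 2 they were GDF15 (3.58) and the metalloproteinase gene MMP3 (-3.14) in HBL100 and SLAMF7 (2.65) in MCF10A. Among the lines with 1 or 2 calls they were APOBEC3B (0.33) in SUM149, HFE (-0.84) in AU565, CCDC170 in BT474 (-2.14) and CAMA1 (2.21), ICMT (-0.55) in BT549, PRDM13 (-1.10) in DKAT and the histone gene H2AC6 (-0.83) in HCC1954. With each series fitted separately, 10 of the largest called changes of the lines lost their call and 11 kept it. MCF10A then had 3 called genes, against 94. All changes named for the lines with 1 or 2 calls and SLAMF7 in MCF10A were among those lost. With the block added to that fit, those in AU565, CAMA1, BT549, DKAT, HCC1954 and MCF10A passed.

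The F test called 1037 of 11963 genes as responding differently between lines. The 10 with the largest SD over lines were HMMR (SD 1.19), ASPM (1.17), GDF15 (1.15), CENPE (1.09), DLGAP5, CENPF, BUB1, KIF14, SHCBP1 and KIF23 (0.89), most of which act in mitosis. Fitted by itself, series 1 gave 2285 genes and series 2 gave 29, and with the replicate block these were 1662 and 2463, so which series differed more depended on the block. Letters paired the arrays in 7 of the 10 lines of series 2 and in none of series 1.

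**Figure D4:**
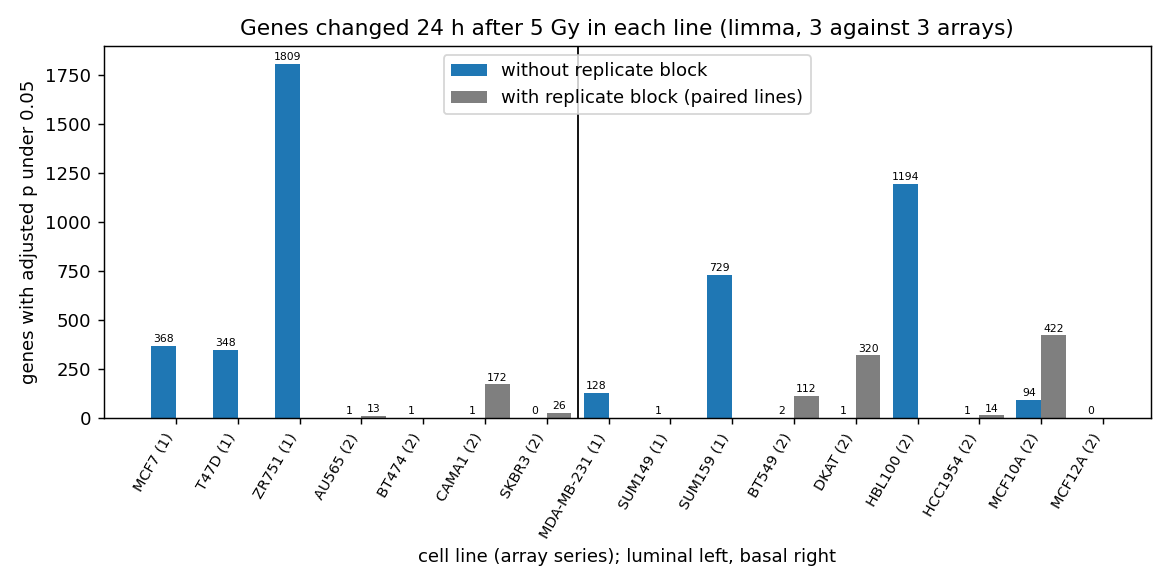
Number of genes with a limma adjusted p under 0.05 (y axis, bars from 0) in each line (x axis, array series in brackets), without the replicate block (blue) and, for the 7 lines whose letters paired the arrays, with it (grey). Counts run from 0 in MCF12A and SKBR3 to 1809 in ZR751, and in DKAT the block raised the count from 1 to 320.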

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

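The outlier rules were fixed before the values were seen, whereas the tests of exchanged HBL100 and MCF12A arrays, of the scale of series 2, of the spread, of a smaller response and of a shift common to all probe sets were chosen after the results they address.

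HBL100 stood apart from the other 8 basal lines in 6 outlier tests (Dixon). The 48 tests run covered luminal and basal lines separately, so HBL100 entered only the basal ones. Its p53 targets changed by 0.75 (others -0.06 to 0.32), MDM2 by 1.05 (-0.31 to 0.36), type I interferon response by 0.70 (-0.13 to 0.19), apoptosis genes by 0.23 (-0.07 to 0.08), cholesterol and fatty acid synthesis by -0.49 (-0.09 to 0.10) and mesenchymal markers by -0.34 (-0.09 to 0.05). Mitosis changed by -1.12 in MCF10A (other basal lines 0.06 to 0.63) and by -2.24 in ZR751 (other luminal lines -0.33 to 0.74). The remaining outliers were the HER2 amplicon in MCF7 (0.13, others -0.00 to 0.03), ESR1 in T47D (-0.57, others 0.03 to 0.19), KRT5 in ZR751 (0.19, others -0.06 to 0.02) and luminal markers in SUM149 (-0.16, others -0.06 to 0.04). The 48 tests gave 12 outliers where 2.4 would arise by chance. The tests were not independent, since MDM2 is also a p53 target and some lists share genes. They also pooled both array series, whose sizes of change are on different scales. The F test over lines called 1037 genes, and 25 of 3151 probe sets without a single gene symbol passed in the response over all lines (5 higher, 20 lower).

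The p53 targets rose in HBL100 by 0.75 and averaged 0.08 in MCF12A, although MCF12A is a line known with normal p53 and HBL100 carries a viral antigen that binds p53. An exchange of some of the arrays between the 2 lines was excluded: 11 basal markers averaged 9.23 in MCF12A and 7.69 in HBL100 with an SD of 0.02 over 6 arrays in each, and the lowest MCF12A array lay 1.496 above the highest HBL100 array. An exchange of all 6 arrays of each is excluded only if MCF12A is the line with the higher basal markers. The prediction took that as given, and it was not tested here. The scale given to series 2 stays open for the size of the change: the median p53 target change of its other lines was 0.00925, but the bound written for that value was wrong, since a positive factor leaves a change near 0 near 0. Such a factor keeps the sign, and 21 of 22 members were positive in HBL100 and 15 of 22 in MCF12A. Exchanged 0 Gy and 5 Gy arrays of MCF12A were excluded, as no array lay beyond those of the other dose by over the spread within its own (value -0.0828).

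Fewer genes were called in the lines of series 2. Spread shared by arrays with the same letter may account for part of it: with each series fitted separately the series 2 calls went from 941 to 5520 with the block, a ratio of 5.87, of which HBL100, whose letters do not pair its arrays, held 938 and 3638 and the 7 paired lines 3 and 1863. Spread pooled over both series is not excluded. Without the block, separate fits lowered the series 2 calls from 1295 to 941, a ratio of 0.727, of which HBL100 held 1194 and 938. Among the paired lines with the block, separate fits raised the calls in DKAT (320 to 712), MCF10A (422 to 593) and BT549 (112 to 262). The same held for CAMA1 (172 to 235) and SKBR3 (26 to 44), whereas AU565 (13 to 5) and HCC1954 (14 to 12) had fewer. A smaller response of those lines remains open, because the difference of medians (403 against 139.5 genes) was as large in a share of 0.186 of 8008 splits. The bound first written for that test was wrong and its reading was changed after the value was seen, since with 6 and 10 lines tied to series a p above the threshold does not show equal responses.

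The response over all lines was made of small changes in the same direction. A shift common to all probe sets of the irradiated arrays was excluded, as 128 of the 150 genes stayed called with arrays centred on their median. Agreement of the array series by chance was unlikely but not excluded. Of 1555 genes with an unadjusted p under 0.05 in series 1, 71.0% had the same direction in series 2. A share of 0.0205 of 1024 sign changes of the lines did as well (median 50%, highest other 75.2%, above the real share).

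Labels were exchanged to see how many calls other groupings give. The real grouping alone (1 of 100) gave as many calls for the response over all lines (150, highest other 0) and the basal response (26, highest other 1). The same held for the subtype difference at 0 Gy (1368, highest other 5). Counts this high were rare under other groupings in this fit, but 100 groupings cannot exclude chance. With the trended and robust prior the counts for all lines and for basal lines were 0. Where the real count was 0, every split had as many: 100 of 100 for the luminal response (highest other 1), 100 of 100 for the subtype difference in response (highest other 0) and 35 of 35 for the Her2 label (highest other 0). Exchanging doses within lines, the real labels were 1 of 10 for the calls per line (4678, highest other 3459) and 1 of 10 for the F test (1037, highest other 420). Those 10 splits are too few for a share under 0.05. The other splits that parted all 3 pairs of letters gave at most 52 calls. The splits that parted 1 pair gave up to 3459, with the highest counts in HCC1954 (1856) and MCF10A (1365), where structure by letter may account for them, but also up to 423 in SUM159 and 250 in HBL100, whose letters do not pair the arrays.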

How the results depend on the processing

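With 16 lines and 3 arrays per line and dose, counts of called genes moved strongly with the fit. Directions of the named genes held wherever a call was made, but 21 list results turned. Among called lists it was 5 of 35 in series 2, 2 of 35 in series 1 and 3 of 43 without ZR751. Fitting each series separately, combining their z values, the Her2 difference within series 2, the TP53 comparison within series, and the relations below the gap were added after the data were seen, the rest was set before. The cause of a moved count was not tested unless stated.

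The response over all lines (150 genes) gave 714 with the line as a random block, 271 with the array series as covariate, 355 among genes above the median level, 371 with z combined, 0 with the trended and robust prior, 0 in series 1, 2 in series 2, 9 without MCF10A, MCF12A and HBL100, 56 to 198 without 1 line and 23 to 67 without 1 replicate. The luminal response (0 genes) gave 48 with the random block, 3 with z combined, 1 with the mean of probe sets, 2 without MCF10A, MCF12A and HBL100, 0 to 8 (BT474) without 1 line and 0 to 1 without 1 replicate. The basal response (26 genes) gave 210 with the random block, 112 with z combined, 62 above the median level, 7 with every probe set, 0 with the trended and robust prior, 0 in series 1, 1 in series 2, 15 without HCC1954, 0 without MCF10A, MCF12A and HBL100, 0 to 90 (ZR751) without 1 line and 0 to 6 without 1 replicate. The subtype difference at 0 Gy (1368 genes) gave 2348 with every probe set, 896 above the median level, 906 without MCF10A, MCF12A and HBL100, 108 in series 1 and 504 in series 2. The Her2 difference (0 genes) gave 1 without MCF10A, MCF12A and HBL100, 0 to 1 (BT474) without 1 line and 0 without any replicate. The fit with the line as a random block had no term for responses that differ between lines. It counted the 3 arrays of a line and dose as separate repeats of the dose. Its higher counts (714, 48 and 210) are therefore not stronger evidence for a response shared by the lines.

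Calls per line (4678 in sum) gave 7092 with every probe set, 2128 to 3520 without 1 replicate, 13148 with the replicate block and 9226 with the block in separate series. The F test (1037 genes) gave 4325 with the block and 364 to 504 without 1 replicate. Letters paired the arrays in 7 lines only (same-letter r over 0.1). In the other 9 the block gave 1460 in T47D, 3183 in ZR751, 1161 in MCF7, 999 in MDA-MB-231, 2477 in SUM159, 23 in SUM149, 2 in BT474, 2753 in HBL100 and 11 in MCF12A, which the letters do not justify.

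Of 43 called lists 3 held with an estimated correlation: 2 of 9 at 0 Gy, 1 of 9 in luminal lines, and 0 of 8 over all lines, 0 of 4 in basal lines, 0 of 5 for the subtype difference and 0 of 8 for Her2. Fry called 1 list over all lines, 1 in luminal lines, 0 in basal lines, 0 for the subtype difference, 1 for Her2 and 8 of the 9 at 0 Gy, in all 11 of the 43. Without genes shared between lists 41 of the 43 stayed called, and apoptosis was lost over all lines (0.0652) and for Her2 (0.253). For the subtype difference in response (5 lists), 10 were called in series 1, 8 in series 2, 9 without MCF10A, MCF12A and HBL100, and 2 (MCF7) to 9 (HBL100) without 1 line, with 3 without ZR751 and 8 without SUM159, AU565 or CAMA1. In basal lines (4 lists) it was 2 without MCF10A, MCF12A and HBL100 and 3 (HBL100) to 7 (ZR751) without 1 line.

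Turned directions: for the subtype difference, without ZR751 mitosis (adjusted p = 0.0112) and DNA replication (0.166), and in series 2 DNA replication (2.39e-08), double-strand break repair (3.83e-05), mitosis (1.26e-05), p53 targets (0.000169), interferon response (0.00921) and lysosome (0.0870). In luminal lines mitosis turned without ZR751 (3.86e-11) and in series 2 (1.78e-13), as did double-strand break repair (0.000412), which over all lines had 0.882 in series 2. In series 1 mitosis turned over all lines (0.00181) and at 0 Gy (0.00233), p53 targets (0.727) and interferon (0.875) at 0 Gy and histones in basal lines (0.0461). Basal p53 targets turned without MCF10A, MCF12A and HBL100 (0.901) and Her2 mitosis without ZR751 (0.884). Within series 2 (3 lines against CAMA1) Her2 mitosis (3.13e-05) and p53 targets (0.995) turned, with 0 genes called, and 4 lists instead of 8.

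Adjusted p of lists over the lines and replicates left out ran, for the subtype difference, from 1.78e-05 (BT474) to 0.284 (MCF7) for DNA replication and from 1.87e-07 (MCF10A) to 0.0795 (replicate C) for mitosis, for Her2 mitosis from 3.54e-13 (CAMA1) to 0.884 (ZR751), and for luminal mitosis from 3.86e-11 (ZR751) to 0.351 (MCF7). Calls lost with a line left out were, for the subtype difference, DNA replication without MCF7 (0.284), SUM149 (0.0708) or HCC1954 (0.0654), mitosis without MCF7 (0.0569), and lysosome without MCF7 (0.0868), ZR751 (0.575) or replicate C (0.118). They were also luminal double-strand break repair without ZR751 (0.580), apoptosis over all lines without HBL100 (0.0510), and basal p53 targets (0.211) and interferon response (0.103) without HBL100. For Her2, apoptosis was lost without BT474 (0.129), CAMA1 (0.0662), MCF7 (0.110), ZR751 (0.0594) or replicate A (0.0696).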

Other observations

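The gap that separates lines by p53 target change (0.08 to 0.32) and the relations below it were chosen after the values were seen. The test of lines named as having normal TP53 was fixed before, its prediction was written after.

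ZR751 and MCF7, both luminal and oestrogen receptor positive by background, shared much of their response. Both raised 65 genes (10.7 by chance) and lowered 176 (17.5 by chance), with 4 opposite and r = 0.54 across genes. T47D, also luminal and oestrogen receptor positive, shared less with either: r was -0.09 with ZR751 (68 genes opposite, 20 raised and 17 lowered in both, 10.9 and 15.6 by chance) and -0.12 with MCF7 (36 opposite, 5 and 2 in both, 2.05 and 3.38 by chance). MCF10A, a line not derived from a tumour, shared 83 falls with ZR751 (7.22 by chance, r = 0.48) and 24 with MCF7 (1.57 by chance), but without replicate A or B MCF10A had only 4 and 0 calls by limma in all. HBL100 shared 104 rises (50.3 by chance) and 95 falls (38.3 by chance) with ZR751, but 58 genes went opposite ways and r was 0.03. It shared 31 rises (9.43) and 43 falls (8.30) with MCF7, with 11 opposite. MDA-MB-231 and SUM159 shared 18 falls (3.20 by chance) and 6 rises (1.00 by chance), r = 0.51. Their p53 target means were near 0 (-0.01 and -0.00), although in SUM159 CDKN1A rose and FAS fell. The overlap of these 2 lines is not firm either, as SUM159 had 1 call without replicate A and MDA-MB-231 2 and 8 without B or C. No pair shared control arrays.

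GDF15, a cytokine induced by p53 and by stress, rose by 3.58 in HBL100 and by 2.19 in ZR751. These lines are in different array series, so the 2 sizes are not on the same scale. CCDC170, a gene beside ESR1 on the chromosome, fell by 2.14 in BT474 and rose by 2.21 in CAMA1. Neither call was firm: that in BT474 was lost with quantile normalization, with the replicate block (adjusted p = 0.0900) and without replicate A or B, and that in CAMA1 without replicate A or B. Both were lost with each series fitted separately without the block. Among the genes named for the smallest p-values of the subtype difference, SERPINA3 had the largest difference (mean 0.66 in luminal and -0.13 in basal lines). It did not pass (limma adjusted p = 0.857).

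The p53 target response may depend on TP53 status. The 4 lines named beforehand as having normal TP53 (ZR751, MCF7, MCF10A, MCF12A) averaged 0.45 (SD 0.31) against 0.06 (SD 0.22) in the 12 others, a difference of 0.39 (exact p = 0.0137 over 1820 splits), and other ways of scoring gave 0.32 to 0.40 with exact p from 0.00824 to 0.0176. These splits exchanged lines between the array series. Within series 1 the difference was 0.68 (2 against 4 lines, exact p = 0.0667 over 15 splits, the smallest possible), and within series 2 it was 0.11 (2 against 8, exact p = 0.667 over 45 splits). Exchanging lines only within a series gave 0.37 (exact p = 0.0207 over 675 splits), which was added after the values were seen and comes mainly from series 1. HBL100 is among the 12 with 0.75, and MCF12A among the 4 with 0.08, so TP53 status by itself does not order the lines. The status was taken from general knowledge and was not measured here. Sequencing TP53 and blotting p53 and CDKN1A protein at 2 to 24 h in HBL100 and MCF12A would test it.

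Among the 12 lines below the gap no relation passed after adjustment. Their p53 target means spanned only -0.06 (DKAT) to 0.08 (MCF12A), so these tests cannot decide whether the lists are related over all lines. The p53 target mean had r = -0.31 with mitosis (permutation p = 0.328, adjusted p = 0.492), r = 0.51 with DNA replication (permutation p = 0.0889, adjusted p = 0.267; rank correlation 0.67, permutation p = 0.0201, adjusted p = 0.0602) and r = 0.13 with interferon response (permutation p = 0.680, adjusted p = 0.680). Without the 2 farthest lines r was -0.37, 0.62 (rank correlation 0.72, permutation p = 0.0229, adjusted p = 0.0688) and 0.22, and in the 8 lines of series 2 it was -0.49, 0.44 and 0.30. The lines above the gap had DNA replication means of -1.55 (ZR751), -0.79 (MCF7), -0.65 (MCF10A) and -0.47 (HBL100). The lowest below the gap were -0.22 in series 1 (MDA-MB-231) and -0.30 in series 2 (BT549). This order is opposite to the positive r with DNA replication below the gap. Correlations over all lines are not given here.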
